A study of Homo sapiens with 6 samples.

How the data were processed

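Total RNA of 3 control and 3 cadmium-exposed samples of BEAS-2B cells was amplified with random primers and labelled with Cy3, per the labels' protocols, and hybridised to one-colour Agilent-format arrays with 62903 spots. The spot values are intensity values deposited by the authors, made with Agilent Feature Extraction version 11.0.1.1 per the submitters' processing notes. The processed signal is background-subtracted and corrected for spatial trends, per the file headers, and not normalized between arrays. The deposited value table of the series holds log2 values. Set against the scanner's values, it had a slope between 0.96 and 1.07 on log2 processed signal, so its probes were not centred and it runs in the direction of signal. Every array had the same median, 6.69, and the same 75th percentile, 8.46, as quantile normalization over the 6 arrays would give. What the authors did to make this table is not given in the sources used here. It was used as an alternative.

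The 1439 control spots and 360 spots of the array maker's negative probes were left out, which left 60924 probes. Spots that the scanner software marked as outliers, 99 of them on any array, were treated as missing, and none was saturated. Spots of the same probe were averaged as log2 of the processed signal. The 75th percentile of each array was then subtracted. This percentile was 495, 495.1 and 322.9 in control replicates 1, 2 and 3, and 247.3, 350.1 and 376 in cadmium replicates 1, 2 and 3, against a median local background between 19 and 30. Probes well above background on at least 3 of the 6 arrays were kept, 53674 in all, of which 50518 were well above background on every array.

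Groups came from the treatment in the labels. The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term), with Benjamini-Hochberg adjustment over the kept probes and a threshold of 0.05. The same steps were tested on simulated data of 53674 probes with the real spread and group sizes. They recovered 22% of 50 probes changed by 1 on the log2 scale, 86% of those changed by 2, and 100% of those changed by 3 or by 4, with 5 false calls. The simulation drew 6 independent arrays and no slide difference, so these shares do not cover a pair of near-identical controls or the slides. Figures were drawn with matplotlib 3.10.9.

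Slide and scan session were read from the file headers and coincide. Control replicates 1 and 2 share slide 1, and the other 4 arrays share slide 2. Because slide 2 holds both groups, the comparison was also fitted with slide as a block and within slide 2. Pairs of arrays were compared over the probes well above background on all 6, after a smooth trend with signal was removed, by setting each difference against the spot errors of the scanner software. By this measure control replicates 1 and 2 agree within noise, with a mean squared ratio of 0.55 against 1.79 to 6.20 for the other pairs within a group. They were counted as 1 sample in means and SDs, and a fit with both averaged was added.

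Genes were named only through accessions in the files. Of the probes, 20 carry a RefSeq accession, and all 20 matched a symbol in a RefSeq gene table of assembly GRCh38.p14. The array's layout is named for an older build, so no coordinates are given. The other 60904 probes carry a number that the files do not pair with a gene or with a coding or non-coding class. The split by class and the tests of 40 gene lists, planned before the data were examined, were therefore not run: 6 of the 1037 listed genes had a name here, with at most 3 in a list. The rule for named genes, also written before, took the 14 genes most raised and the 14 most lowered among called probes with a gene symbol and non-overlapping groups that were well above background on every array of at least 1 group. It also took up to 4 members of each list described, and DUXAP10 with the Hedgehog genes PTCH1, SMO, GLI1, GLI2 and GLI3, which the study's publication is known to follow. No called probe had a symbol. Of the 20 genes, 18 are given and 2 are not reported here. The 12 of these outside the lists were not chosen by their values. Of the called probes without a gene name, the pair with the highest log2 fold is given by number.

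Alternatives planned before the data were examined were quantile normalization, scaling by the median, the deposited value table, no filter on dim probes, a filter on all 6 arrays, an intensity trend in the prior, array weights, leaving out each array, the replicate number as a block, and slide as a block. Those added after seeing the data were control replicates 1 and 2 as 1 sample, slide 2 alone, outlier spots kept, cyclic loess, and a normexp background correction with an offset of 50 on the median spot signal.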

Results

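RNA was measured in BEAS-2B cells, an immortalised line of human bronchial epithelial cells that serves as a model of the airway lining. One group had been kept for a long period in a low concentration of cadmium chloride, a salt of a toxic metal, and the control group had been grown without it for a matched number of passages. Each group had 3 samples, and each sample was hybridised to 1 one-colour array that carries probes for long non-coding RNAs, transcripts that are not translated into protein. The study asked how long exposure to cadmium changes the expression of these RNAs. Of 60924 probes measured per array, 53674 were well above background on at least 3 of the 6 arrays and were tested. Between 85.7% and 88.1% of the probes were well above background on each array. The labels do not say whether the samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

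Control replicates 1 and 2 differed by less than the measurement noise that the scanner software gives for each spot. Only 1.75% of the probes differed between them by more than the 95% bound of that noise, against 8.10% to 35.7% for the other pairs of arrays within a group. On 1 array, the 10 spots of a probe with an accession varied less, with a median SD of 0.033 on the log2 scale. The median absolute deviation of the log2 difference between control replicates 1 and 2 was 0.11. The software's noise may thus be a wide measure, and it cannot show that both arrays hold the same RNA. As a precaution, control replicates 1 and 2 were counted as 1 sample, and control means and SDs below have n = 2. The 6-array fit chosen before the data were examined counts them separately, and the result with both averaged is given beside it.

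A small set of probes was far higher in the cadmium-exposed cells. With limma on all 6 arrays, 19 probes were higher at an adjusted p under 0.05, all of them by at least 2-fold, and 0 were lower. With control replicates 1 and 2 as 1 sample, 6 of these 19 were called, and 0 were lower. Leaving out 1 array moved these counts to between 5 and 4298 higher and between 0 and 5836 lower, with the highest counts without control replicate 3, and with 41 higher and 5 lower without cadmium replicate 2. At an unadjusted p under 0.05 (limma) there were 5353 probes, 9.97% of those tested, where chance gives a share of 0.05. This share does not single out cadmium. Control replicates 1 and 2 with cadmium replicate 1, 2 or 3 against the rest gave 7.78%, 16.5% and 33.4%. On each of the 19 probes, every cadmium array lay above every control array, which a call on these same arrays favours. Over all tested probes, 13.03% had groups that did not overlap, against the 10% that chance gives for 3 samples against 3. With control replicates 1 and 2 as 1 sample the share was 14.7%, below the 20% that chance gives for 2 against 3. In 15 of the 19, at least 1 control array was well above background, and the folds of these 15 ran from 3.52 to 40.3. All 3 control arrays were well above background in 13 of the 19. The rest of the 15 had folds of 6.88 and 7.99, which rest in part on control arrays near background. In the remaining 4 of the 19, no control array was well above background while every cadmium array was. These 4 were at least 2.66-fold to at least 8.81-fold higher. Each of these bounds sets the cadmium mean against a control mean in which an array counts at the higher of the probe's own signal and the lowest signal well above background there.

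The files do not pair the 19 probes with gene names, nor say which are non-coding. Of the 19, only the pair with the highest estimates is given here, by number. The probe with the highest estimate, ASHGV40021768, was 40.3-fold higher (log2 fold 5.33, SE 0.51, limma adjusted p = 0.047). Its log2 signal relative to the array's 75th percentile was 1.43 ± 0.59 (SD, n = 2) in control cells and 6.63 ± 1.03 (SD, n = 3) in cadmium-exposed cells. The next, ASHGV40034577, was 39.5-fold higher (log2 fold 5.31, SE 0.48, limma adjusted p = 0.0414), at -0.85 ± 0.35 (SD, n = 2) and 4.38 ± 1.03 (SD, n = 3). Neither passed with control replicates 1 and 2 as 1 sample, where limma gave both an adjusted p of 0.186. With slide as a block neither passed, at limma adjusted p of 0.561 and 0.533 in the same order. The median log2 fold of the 19 was 3.14, and 2.84 with the 4 dim probes at their bound.

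**Figure D1:**
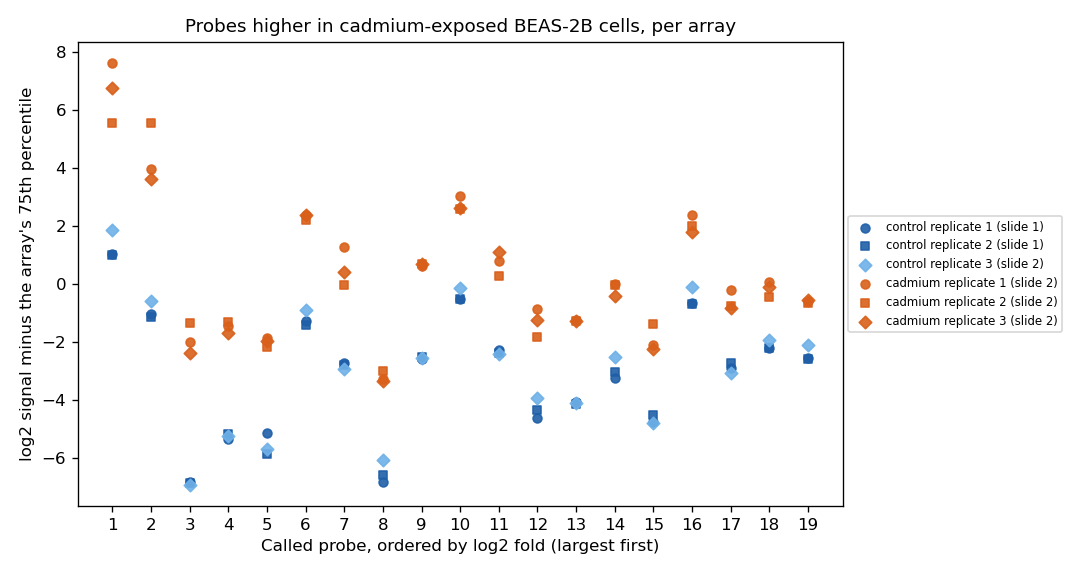
Log2 signal minus the array's 75th percentile (vertical axis) of the 19 probes called higher in cadmium-exposed cells, ordered by log2 fold (horizontal axis), with 1 point per array. Every cadmium point (orange) lies above every control point (blue), including control replicate 3, which shares the slide of the cadmium arrays. The probes were called on these same arrays, which favours such a separation.

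The arrays lay on 2 slides, scanned in 2 sessions. Control replicates 1 and 2 were on slide 1, and control replicate 3 was on slide 2 with the 3 cadmium arrays. With slide as a block, 4 probes were higher and 5 were lower at an adjusted p under 0.05 (limma), and within slide 2, where control replicate 3 stands alone and the cadmium arrays supply all of the spread, 0 were higher and 4 were lower, with 1172 probes at an unadjusted p under 0.05. With control replicates 1 and 2 as 1 sample, where limma gave 6 higher and 0 lower, 1604 probes had an unadjusted p under 0.05. This is a smaller share of the tested probes than the 0.05 that chance gives, and so is the count within slide 2. The 4 probes higher with slide as a block were also among the 19. These 4 were called in those 3 fits, but not within slide 2, where the lowest adjusted p of the 19 was 0.171 (limma). The block fit counts control replicates 1 and 2 separately, and with both as 1 sample it is the contrast within slide 2. Without the block, 3 of these 4 probes had folds between 7.16 and 11.4. With the block, the log2 folds of these 3 were 2.83 to 3.22. The remaining 1, not well above background on any control array, was at least 8.81-fold higher without the block. Over the 15 called probes with a control array well above background, the median log2 fold was 2.998 without slide as a block. With the block it was 2.89, and their estimates lay between 1.50 and 4.98. The 19 were called without the block, which favours probes on which control replicate 3 lies near the other controls. The closeness of these medians is therefore not a separate check on slide. Of the 5 probes lower with slide as a block, 4 lay in a patch of adjoining bright spots on control replicate 3, as did all 4 within slide 2.

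The files give an accession for 20 probes, all of them for protein-coding transcripts, and each was printed on 10 spots per array. Of these, 18 are reported here. None of the 18 genes passed the test: the lowest adjusted p was 0.466 over all probes and 0.29 adjusted over the 18 genes alone (limma). The estimate was above 0 for 16 of the 18 genes, but for 4 of 18 with slide as a block and for 5 of 18 with quantile normalization. ACTB, the cytoskeletal beta-actin, had a log2 fold of 0.82 (SE 0.38) on all 6 arrays and -0.07 (SE 0.23) with slide as a block. Its log2 signal relative to the 75th percentile was 9.59 ± 0.95 (SD, n = 2) in control and 10.19 ± 0.27 (SD, n = 3) in cadmium-exposed cells. ACTG1, the gamma-actin, and PFN1, the actin-binding profilin, had log2 folds of 0.67 and 0.40, and -0.07 and -0.20 with the block. RACK1, a scaffold protein of the ribosome, had 0.78 and 0.07, and EIF3D, a translation initiation factor, had 0.57 and -0.03.

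Among the gene lists fixed before the data were examined, 3 of 40 held any of these genes. From the ribosomal protein list, RPS18 had a log2 fold of 0.69 (0.37 SE), RPLP1 of 0.62 (0.38 SE) and RPL10 of 0.10 (0.15 SE), and 0 of 3 passed, over all probes or adjusted over the list alone. With slide as a block they had -0.10, -0.19 and 0.01. From the hypoxia and glycolysis list, the glycolytic enzymes GAPDH and PGK1 had 0.68 (0.35 SE) and 0.45 (0.22 SE), and -0.07 and 0.04 with the block, and 0 of 2 passed. From the respiratory chain list, COX4I1, a subunit of cytochrome c oxidase, had 0.47 (0.32 SE), and -0.12 with the block. A list needed 5 named genes for a test of the whole list and none had them, so the metallothionein, oxidative stress, Hedgehog, epithelial and other lists were not analysed here. The same holds for DUXAP10, PTCH1, SMO, GLI1, GLI2 and GLI3.

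The remaining named genes had estimates on both sides of 0. H3-3A, a histone H3 variant, had a log2 fold of 0.35, the dynein light chain gene DYNLL1 0.34, the arginine methyltransferase gene PRMT1 0.29, the mitochondrial import gene MTX1 0.27, and ARHGDIA 0.19. With slide as a block, these were -0.21, -0.28, -0.30, -0.16 and -0.18 in the same order. ODC1, the first enzyme of polyamine synthesis, had -0.10, and -0.31 with the block. GRM4, a glutamate receptor gene, had -0.56 (0.42 SE), and 0.19 with the block. The slide term of the block fit, which sets control replicate 3 against control replicates 1 and 2, was above 0, higher on slide 2, for 17 of the 18 genes, with a log2 difference of 1.34 for ACTB and of -1.14 for GRM4.

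**Figure D2:**
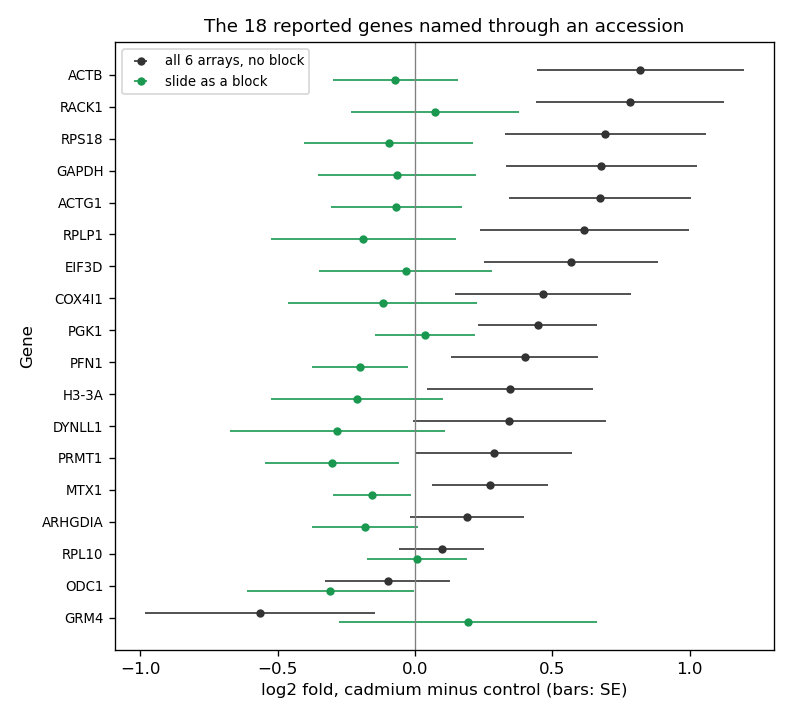
Log2 fold, cadmium minus control (horizontal axis), of the 18 named genes (vertical axis), with all 6 arrays and no block (black) and with slide as a block (green); bars are SE. Estimates are above 0 for 16 genes without the block, for 4 with it and for 5 with quantile normalization, which is not drawn.

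Over all tested probes, control replicate 3 was closer to the cadmium arrays of its slide than to the other controls. The first principal component held 63.9% of the variance and placed control replicates 1 and 2 at -83.5 and -84.2, control replicate 3 at 39.5, and cadmium replicates 1, 2 and 3 at 97.9, 22.0 and 8.32. The median absolute deviation of the log2 difference was 0.11 between control replicates 1 and 2. It was 0.62 and 0.63 between each of them and control replicate 3, and 0.24 to 0.35 between control replicate 3 and the cadmium arrays. Across slides, control replicates 1 and 2 were at 0.44 to 0.79 from the cadmium arrays. Between cadmium arrays it ran from 0.21 to 0.45, with cadmium replicate 1 the farthest from the others. The difference between control replicate 3 on slide 2 and the controls on slide 1 moved with signal, and slide and sample cannot be told apart in it. Over 10 equal bins of the probes, from the dimmest to the brightest, its median on the log2 scale ran from -0.34 to 0.69. The cadmium arrays differed from control replicate 3 by 0.12 to -0.10 over the same range.

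**Figure D3:**
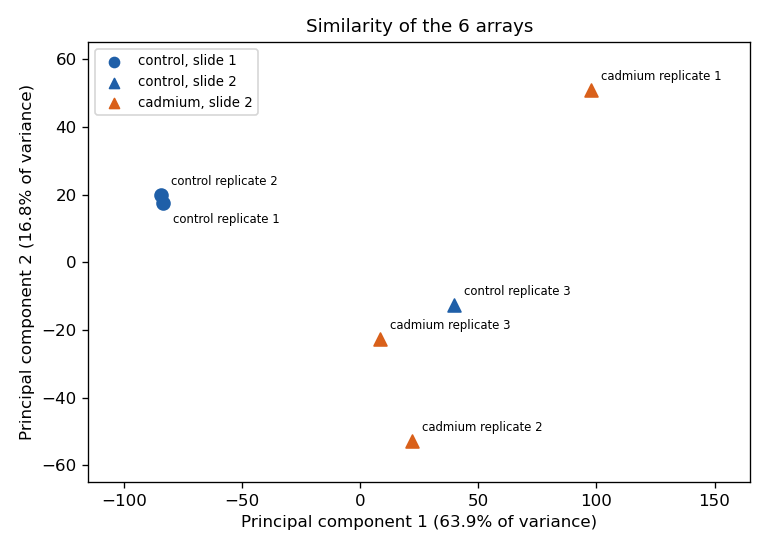
First (horizontal, 63.9% of variance) and second (vertical, 16.8%) principal component of the 6 arrays, coloured by group and shaped by slide. Control replicate 3 lies among the cadmium arrays of its slide, and control replicates 1 and 2 lie together at -83.5 and -84.2 on the first component.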

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

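All comparisons in this part were chosen after the values were seen. The arrays carry control probes that the comparisons of the report do not use, and for 5 of 9 families of them all 3 cadmium arrays lay above all 3 control arrays in mean log2 signal relative to the 75th percentile. The difference, cadmium minus control with control replicates 1 and 2 as 1 sample, was 0.455 for the human GAPDH and PGK1 control probes, 0.33 for the mouse and 0.18 for the rat probes of the same genes, 0.17 for the E1A probes and 0.16 for the DCP probes. In 1 family, the dark corner spots, all cadmium arrays lay below all control arrays (-0.20), and in the other 3 the groups overlapped, with differences of -0.093 (ERCC), -0.12 (ETG) and -0.15 (negative probes). The human, mouse and rat probes are of the same genes, so these families are not separate observations. For the human probes the lowest cadmium array stood at 5.63 and control replicate 3, on the same slide, at 5.62. Control replicates 1 and 2 on slide 1 stood at 4.89 and 4.86. For the mouse probes control replicate 3 stood at 1.30, and control replicates 1 and 2 at 0.92 and 0.88. Control replicate 3 was also the highest control for the rat and DCP probes, but the lowest for the E1A probes. The E1A probes were at -4.09 to -4.47 on the 6 arrays, near the negative probes at -4.10 to -4.57.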

How the results depend on the processing

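The settings with control replicates 1 and 2 as 1 sample, slide 2 alone, cyclic loess, outlier spots kept and normexp were chosen after seeing the data. With all 6 arrays and no block, limma called 19 probes higher and 0 lower. The count of higher probes stayed within 1.5 times of that with quantile normalization (17), the authors' value table (21), cyclic loess (23) and outlier spots kept (19), each with 0 lower, and 15, 16, 17 and 19 of the 19 probes were among them. It was 8 with normexp, 11 with median scaling, 9 with no filter on dim probes, 6 with a filter on all 6 arrays and 6 with control replicates 1 and 2 as 1 sample, each with 0 lower and each also the count at 2-fold; the cause was not tested. An intensity trend in the prior gave 31 higher and 3 lower, all by at least 2-fold. Slide as a block gave 4 higher and 5 lower, and slide 2 alone 0 higher and 4 lower, again all by at least 2-fold. Array weights gave 12703 higher and 14794 lower, and 1125 and 1181 by at least 2-fold. The weights were 6.10, 3.40 and 0.12 for control replicates 1, 2 and 3 and 0.21, 1.71 and 1.19 for cadmium replicates 1, 2 and 3. The control side of this fit therefore rests mostly on the near-identical control replicates 1 and 2 of slide 1. Slide and group can hardly be told apart in it, and what else moved the counts was not tested. Leaving out each array gave 5 to 4298 higher and 0 to 5836 lower, and 5 to 1139 and 0 to 1108 by at least 2-fold. The highest values came without control replicate 3, where slide and group cannot be told apart, and without the other arrays the counts were 8 and 6 higher (control replicates 1 and 2), 7 and 5 higher (cadmium replicates 1 and 3), and 41 higher with 5 lower (cadmium replicate 2).

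The labels do not say that shared replicate numbers pair the samples. The deviations of same-numbered samples from their group means correlated over probes at -0.42, 0.11 and -0.54 for numbers 1, 2 and 3. No sample correlated best with its own number, but this cannot decide the pairing. Control replicates 1 and 2 are near-identical, so the control deviations mostly set that pair against control replicate 3 on the other slide. With cadmium replicate 1, control replicates 1, 2 and 3 correlated at -0.42, -0.40 and 0.47. The fit with the replicate number as a block called 5 higher and 0 lower, and 5 and 0 by at least 2-fold.

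Both probes given by number kept their direction in each of the 20 alternatives, with log2 folds of 4.78 to 5.88 for ASHGV40021768 and 4.72 to 5.78 for ASHGV40034577. The calls were lost in 12 and 13 of them, and the limma adjusted p ran from 0.000905 to 1 and from 0.0013 to 1. None of the 18 named genes passed in any setting except array weights (16 genes) and without control replicate 3 (8 genes). In those settings the controls rest mostly or wholly on slide 1. Several changed sign. With slide as a block and, as the same contrast, in slide 2 alone, the log2 fold was -0.096 for RPS18, -0.034 for EIF3D, -0.19 for RPLP1, -0.12 for COX4I1, 0.19 for GRM4, -0.16 for MTX1, -0.066 for GAPDH, -0.28 for DYNLL1, -0.18 for ARHGDIA, -0.071 for ACTB, -0.21 for H3-3A, -0.068 for ACTG1, -0.30 for PRMT1 and -0.20 for PFN1. With quantile normalization and with the authors' value table, in that order, it was -0.032 and -0.028 for RPS18, -0.15 and -0.13 for RPLP1, -0.022 and -0.019 for COX4I1, -0.065 and -0.067 for MTX1, -0.0075 and -0.0074 for GAPDH, -0.17 and -0.17 for DYNLL1, -0.24 and -0.22 for ARHGDIA, -0.032 and -0.030 for H3-3A, -0.066 and -0.084 for ACTG1, -0.17 and -0.17 for PRMT1, and -0.12 and -0.12 for PFN1. With cyclic loess it was -0.0072 for RPLP1, -0.093 for COX4I1, -0.14 for MTX1, -0.22 for DYNLL1, -0.33 for ARHGDIA, -0.17 for H3-3A, -0.27 for PRMT1 and -0.16 for PFN1. Leaving out each array moved ODC1 between -0.324 and 0.0155. The median log2 fold of the 18 genes was 0.423 with percentile scaling and no block, and 0.473 with median scaling. It was -0.0486 with quantile normalization and -0.0503 with cyclic loess, which can shift bright and dim probes by different amounts. Between control replicate 3 and the other controls, the median log2 difference ran from -0.342 in the dimmest bin to 0.686 in the brightest. The positive folds thus depend on how a shift with signal is treated. Slide and sample cannot be told apart in that shift, and other causes were not tested.

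The planned normexp correction on mean spot signal was not run, as that column is not in the files used, and the median signal took its place. The split into coding and non-coding probes, the gene list tests with their alternatives (an estimated correlation, fry, the mean over probes) and the comparison of several probes of a gene were not run, for want of gene names. Signal over background limits the 4 called probes that were not well above background on any control array to a bound.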

Other observations

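All tests in this part were chosen after the results they bear on were seen. The raised probes were not spread evenly over the array maker's probe numbers. Of the 19, 6 had another of the 19 within 10 numbers, in a run of 4 and a pair, and the highest count in 10000 random draws of 19 probes was 4 (permutation p = 1e-04, the smallest these draws can give). The run of 4 spans 8 consecutive numbers, 7 of them tested. Of the 4, 3 had log2 folds of 2.55 to 3.52, and 1, not well above background on any control array, was at least 6.54-fold higher. Another probe of the run had a log2 fold of 2.29 without passing (limma adjusted p = 0.0881), and the other 2 tested probes had -0.48 and 0.04. Neighbouring numbers were not neighbouring spots: the nearest such probes lay 34 rows or columns apart, so a mark on the glass does not account for the runs. A candidate explanation, untested because the files do not say how numbers were given, is that neighbouring numbers belong to transcripts of the same locus; over all tested probes the log2 folds of consecutive numbers correlated only weakly (r = 0.09 across probes, and 0.02 at a distance of 100 numbers).

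Because control replicate 3 shares the slide of the cadmium arrays, it can show whether slide alone gives a difference. Of 36 probes at least 4-fold higher on every cadmium array than on control replicates 1 and 2, chosen without control replicate 3, that array lay nearer to the other controls on 35, with a median position of 0.17 between the control mean at 0 and the cadmium mean at 1, which argues against slide as the cause of these rises. Of 6 probes at least 4-fold lower, it lay nearer to the other controls on 0 (median position 0.95), and of 373 at least 2-fold lower on 18 (median 0.97), so these differences are consistent with slide, or with a difference between the control samples, which the design does not separate from it. Of 403 at least 2-fold higher, it lay nearer to the other controls on 176 (median 0.57), which leaves a mixture, part of which may come from either. With 10 splits of the 6 arrays, chance cannot be tested below a share of 0.05. The real split alone gave as many as 19 called probes, and the highest of the others gave 1. Splits that part the near-identical control replicates 1 and 2 could hardly call a probe. In these, at most 1.09% of probes had an unadjusted p under 0.05 (limma). The split of control replicates 1 and 2 with cadmium replicate 3 against the rest had 17926 probes at that threshold, against 5353 in the real split. With cadmium replicate 2 in its place there were 8832, and with cadmium replicate 1 there were 4177. This structure of the samples follows slide in part. A response to cadmium stays open as a hypothesis for the 4-fold rises, beside a difference between cultures, which was not tested.

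On control replicate 3, 8 spots were more than 5 log2 units brighter than on any other array. Of these, 7 lay within 2 rows and columns of another, between rows 91 and 97 and columns 12 and 14, at 8.03 to 11.1 log2 units above the next array, and the highest count in 10000 random placements was 4 (permutation p = 1e-04, the smallest these draws can give). This is consistent with a local mark on the glass, and the scanner software had marked 3 of the 7 as outliers. They supply 4 of the 5 probes lower with slide as a block and all 4 within slide 2. No biological explanation was tested.

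Cadmium replicate 1 stood apart from its group on some probes. Within slide 2, 644 probes on it lay at least 2-fold below and 315 at least 2-fold above all 3 other arrays, against 140 and 70 for control replicate 3, 100 and 119 for cadmium replicate 2, and 27 and 47 for cadmium replicate 3. The log2 difference between the 3' and 5' control probes of GAPDH was 3.38 on cadmium replicate 1 and 2.25 to 2.74 on the other 5 arrays. For PGK1 it was 5.83 on cadmium replicate 1, within the 5.69 to 5.95 of the others. Whether these differences reflect the quality of the RNA, which was amplified with random primers, was not tested. The probe with the widest range among the cadmium arrays had a log2 signal relative to the 75th percentile of 9.30, -1.85 and -2.98 in cadmium replicates 1, 2 and 3, and of 1.66, 3.20 and 4.63 in control replicates 1, 2 and 3.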
